A study of Mus musculus with 127 samples.

How the data were processed

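Bulk RNA sequencing of LT, ST and MPP sorted from the bone marrow of 4 young and 2 old mice was analysed. The deposited table holds expected counts per gene symbol, which the submitters' processing notes attribute to RSEM (no version stated) on genome build mm9. These deposited expected counts are not scaled to library size. Of the values, 89.5% are whole numbers. The table covers 23366 gene symbols, of which 3532 are at 0 in all 127 libraries. Chromosome positions were not analysed here.

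Groups were taken from the labels: age, mouse number, cell type, course (with LPS and Pam3csk4, or unstimulated) and time. The 0 h libraries of young mice 1 and 2 and old mouse 2 are labelled with LPS and Pam3csk4, except 2 LT repeats of old mouse 2, which are labelled as untreated like those of young mice 3 and 4 and old mouse 4. All were read as 1 baseline without exposure. Of the 127 libraries, 6 of old mouse 2 LT held 7 to 41 counts, under 1000, and were near-empty. The other 121 held, in units of 1e6 counts, 0.991 to 7.73 (median 4.06). Technical repeats of a mouse, cell type and time were summed and rounded, which gave 108 libraries, 75 young and 33 old. The near-empty libraries stayed in the sums, so 16 were made of several deposited ones (up to 4), 12 of them with 2 or 3 usable ones. They were left out where 1 repeat replaced the sum and where repeats were correlated. Between usable repeats the lowest correlation of 12 conditions ranged from 0.26 to 0.94 (Pearson's r across genes, which are not independent replicates). At 0 h r was 0.26, 0.59 and 0.84 in LT of young mice 1 and 2 and old mouse 2. In the same mice r was 0.36, 0.72 and 0.60 in ST and 0.85, 0.89 and 0.94 in MPP. In each of these mice the 0 h repeats of LT and ST correlated less than those of MPP. Reads carry no molecular identifiers, so floors cover counting error only.

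The same mouse number was read as the same animal across cell types and times. Residuals of libraries of 1 mouse correlated at a mean r across genes of 0.192, 0.0684 and 0.408 in young mice 1, 2 and 3, and at -0.104, -0.0336 and -0.195 with those of other mice. Mouse was a block only in a named alternative.

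Counts were fitted in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F tests, 2-sided) and adjusted by Benjamini-Hochberg within each comparison at 0.05. A fit of 63 libraries and 13678 genes gave the changes from 0 h in young mice 1, 2 and 3 and their differences between cell types. A fit of 72 libraries and 14401 genes compared stimulated with unstimulated courses. Fits of 12 libraries (11568 genes) and 18 libraries (12983 genes) gave the differences between cell types and between ages at 0 h. Levels are given as mean ± SD of CPM (counts per 1e6), and changes as log2 ± SE. A fold against a group at 0 counts was computed against a floor of 3 counts over the group. Old mouse 2 was the only stimulated old mouse, so its list medians, of log2(CPM + 1) changes, carry no test.

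The 23 gene lists were written before the data were examined and were tested, with at least 3 members, by camera of limma 3.58.1 with a preset correlation of 0.01 and again with an estimated one; fry was also run. The lists were NF-kB targets, cytokines, interferon-stimulated, immediate early, TLR signalling, SOCS and JAK-STAT, HSC identity, MPP and lymphoid priming, cell cycle, myeloid, megakaryocyte, erythroid, B cell, T and NK cell, stromal, aged HSC, heat shock, integrated stress response, ribosome biogenesis, hypoxia, cholesterol, p53 target genes and 3 regulators followed up in the study. Genes were named by a rule fixed before the data were examined: the 6 largest rises and falls that passed with a mean of at least 10 CPM and the same direction in every mouse, up to 4 members per list, and a fixed set. Ccl3 in ST and MPP, Sqstm1, Vmp1, Ftl1, Aldoa, Faf1 and the genes named for cultures without ligand were chosen after their values were seen.

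Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, DESeq2's size factors, no or a stricter filter (5 CPM), mouse as a block, a fit of the compared libraries alone, 1 repeat in place of the sum, other baselines, and leaving out each mouse. A minimum of 8000 detected genes, ST at 12 h without its shallowest library and the granule share as a covariate were chosen after seeing the data. The steps were tested on simulated data with 200 changed genes: for LT at 2 h edgeR called 10 genes, 0 of them false, and found 15.2% of planted log2 changes of 4, while DESeq2 called 121, 89 of them false, and limma voom 41, 20 of them false. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.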

Results

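RNA of 3 cell populations sorted from mouse bone marrow was sequenced in bulk with SMART-seq2, a full-length cDNA method for small inputs of polyadenylated RNA. The populations were long-term haematopoietic stem cells (LT), short-term haematopoietic stem cells (ST) and multipotent progenitors (MPP), taken from 4 young and 2 old mice. Cells of young mice 1, 2 and 3 and of old mouse 2 were cultured with 100 ng/ml lipopolysaccharide (LPS, a ligand of the Toll-like receptor Tlr4) and 1 ug/ml Pam3csk4 (a synthetic lipopeptide bound by Tlr2). These stimulated cells were collected at 0, 0.5, 1, 2, 4, 8 and 12 h. Cells of young mouse 4 and old mouse 4 were cultured without ligand and collected at 0, 2, 4 and 8 h. The 127 deposited libraries were summed over technical repeats to 108 libraries of 1 mouse, cell type and time each, with 990801 to 11764600 counts (median 4200710). In units of 1e6 counts, stimulated libraries had medians of 4.27 in LT, 4.88 in ST and 4.62 in MPP. Unstimulated libraries had medians of 1.93, 2.17 and 2.36. Between 6241 and 14096 genes had a count in a library. In stimulated LT this number fell between 0 and 8 h from 10101 to 6241 in young mouse 1, from 12319 to 7547 in young mouse 2 and from 12155 to 11501 in young mouse 3. The 0 h libraries of young mice 1 and 2 were sums of 2 repeats, with 6152640 and 11764600 counts, and their 8 h libraries single ones, with 2929420 and 3865140. Single 0 h repeats had 8531 and 7722 detected genes in young mouse 1 and 10620 and 11100 in young mouse 2. Young mouse 3 had 1 library at each time (3658050 and 4568450 counts).

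Transcripts of neutrophil granule proteins differed between mice at 0 h. S100a8, S100a9, Ngp, Camp, Ltf and Lcn2 together made up 5.40% of the LT counts of young mouse 1, 3.12% of young mouse 2, 6.23% of young mouse 4, 1.90% of old mouse 2 and 1.83% of old mouse 4. In young mouse 3 the share was 0.0240%. ST and MPP held between 1.68% and 6.44% in 5 mice and between 0.00988% and 0.0158% in young mouse 3. The log2 ratio of the share in MPP to that in LT ranged from -1.28 in young mouse 3 to 0.05 in young mouse 4. No test was made of this difference, which lies between single mice.

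**Figure D1:**
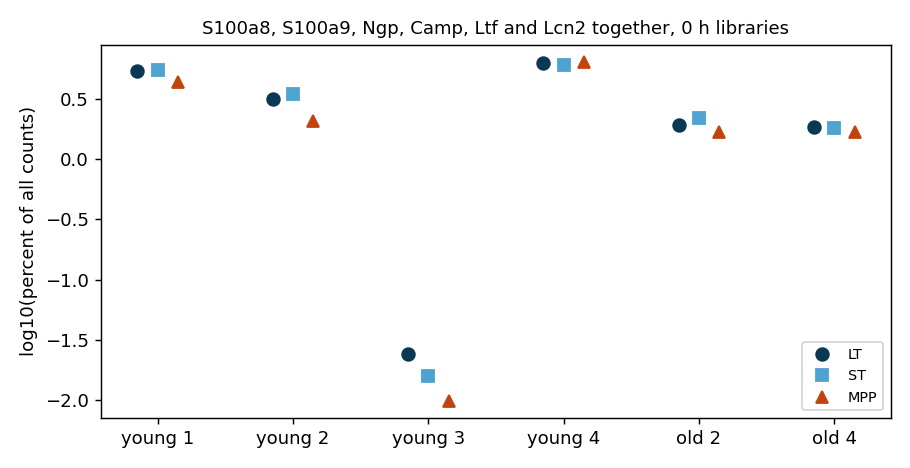
Share of all counts at 0 h held by 6 transcripts of neutrophil granule proteins, as log10 of the percentage, for each mouse (x axis) and cell type (marker). The 3 libraries of young mouse 3 lie between 0.00988% and 0.0240%, and those of the other 5 mice between 1.68% and 6.44%.

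The first comparison asked which genes LT of young mice 1, 2 and 3 change within 2 h of LPS and Pam3csk4, against the 0 h libraries of the same mice. Feedback inhibitors and subunits of the NF-kB pathway rose together. Nfkbiz, a nuclear I-kappa-B protein that NF-kB induces, rose from 11.6 ± 5.86 to 710 ± 71.5 counts per 1e6 (CPM; mean ± SD, n = 3 mice; log2 change 5.99 ± 0.61 SE, edgeR adjusted p = 6.5e-09). Nfkbia, which encodes the inhibitor that holds NF-kB in the cytoplasm, rose from 171 ± 49.1 to 1673 ± 312 CPM (3.35 ± 0.40, adjusted p = 3.3e-07). Tnfaip3, the ubiquitin-editing enzyme A20 that dampens this pathway, rose from 13.1 ± 5.60 to 459 ± 206 CPM (5.17 ± 0.68, adjusted p = 2.3e-06), and Nfkb2 from 30.8 ± 15.2 to 488 ± 58.5 CPM. Of the 24 genes of the NF-kB list, 11 rose, and 22 did when adjusted over the list alone. The list rose by camera with an adjusted p = 7.8e-12 with an estimated correlation.

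Chemokines, immediate early genes and stress genes of LT also rose at 2 h. The chemokine Ccl3 went from 0.720 ± 1.03 to 389 ± 333 CPM (n = 3, log2 change 9.27 ± 1.77 SE, edgeR adjusted p = 0.0029). The neutrophil chemokine Cxcl2, at 0 counts in all 0 h libraries, reached 185 ± 108 CPM, at least 1330-fold higher than a floor of 3 counts over the group (adjusted p = 0.0079). Cd83, a surface protein of activated antigen-presenting cells, rose from 7.02 ± 9.26 to 1618 ± 911 CPM (7.91 ± 1.59, adjusted p = 0.0049), and the cell cycle inhibitor Cdkn1a from 3.98 ± 4.38 to 367 ± 103 CPM. Of the 30 cytokines and chemokines tested, 2 rose, and 17 rose and 1 fell when adjusted over the list alone (adjusted p = 3.9e-05 with an estimated correlation). Of 31 immediate early genes 3 rose (7 adjusted over the list alone; adjusted p = 8.2e-05 with an estimated correlation), among them Nr4a1, a nuclear receptor (4.62 ± 0.79), and Junb, an AP-1 subunit (2.07 ± 0.41). Of 20 p53 target and apoptosis genes 2 rose (3 adjusted over the list alone; adjusted p = 8.6e-04 with an estimated correlation). The integrated stress response list, with 6 of 19 genes higher when adjusted over the list alone, and the heat shock list, with 4 of 16, also rose (adjusted p = 0.0083 and 0.035 with an estimated correlation). Both rose at 2 h without ligand as well, in young mouse 4 and old mouse 4 (5 of 19 and 8 of 16 adjusted over the list alone; adjusted p = 0.0050 and 3.9e-04 with an estimated correlation). The median log2 change of the heat shock list was 1.74 and 1.06 in these mice, against 0.63, 0.73 and 1.29 in young mice 1, 2 and 3.

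Some cytokines and Cd14 did not pass the threshold in LT at 2 h and varied widely between mice. Tnf was at 259 ± 204 CPM against 6.48 ± 9.39 (n = 3, edgeR adjusted p = 0.43). Il1b was at 768 ± 551 against 15.8 ± 13.8 (adjusted p = 0.16) and Cd14, the LPS co-receptor, at 727 ± 635 against 2.93 ± 3.07 (adjusted p = 0.11). Unstimulated LT reached a level of Cd14 within this spread at 2 h, as given below. The list of regulators followed up in the study held Stat3 (598 ± 189 against 259 ± 73.6 CPM), Klf5 (19.6 against 2.01) and Ikzf1 (75.6 against 122). Of these, 0 of 3 passed over all genes and 1 adjusted over the list alone (adjusted p of the list 0.13 with an estimated correlation, and 0.048 with mouse as a block). As the study chose these genes, the count is not independent evidence. Cmtm7 fell from 397 ± 111 to 92.7 ± 32.8 CPM (-2.03 ± 0.43, adjusted p = 0.0082) and Rogdi from 69.0 ± 72.5 to 0.395 CPM. Lists of HSC identity, interferon-stimulated, cell cycle, cholesterol synthesis, ribosome biogenesis, hypoxia, TLR signalling, SOCS and JAK-STAT, aged HSC and MPP genes did not pass at 2 h. Nor did myeloid, megakaryocyte, erythroid, B cell, T and NK cell and stromal markers. Over the 13678 genes tested, 40 were higher and 2 lower than at 0 h by edgeR, and 1305 had an unadjusted p under 0.05. With mouse as a block 101 passed (90 higher), with DESeq2 559 (219 higher and 340 lower). Without libraries of fewer than 8000 detected genes 65 passed, with young mouse 4 added at 0 h 64, and in a fit of these 6 libraries alone 0. Without young mouse 2, 5 genes passed, and without young mouse 3, 112.

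**Figure D2:**
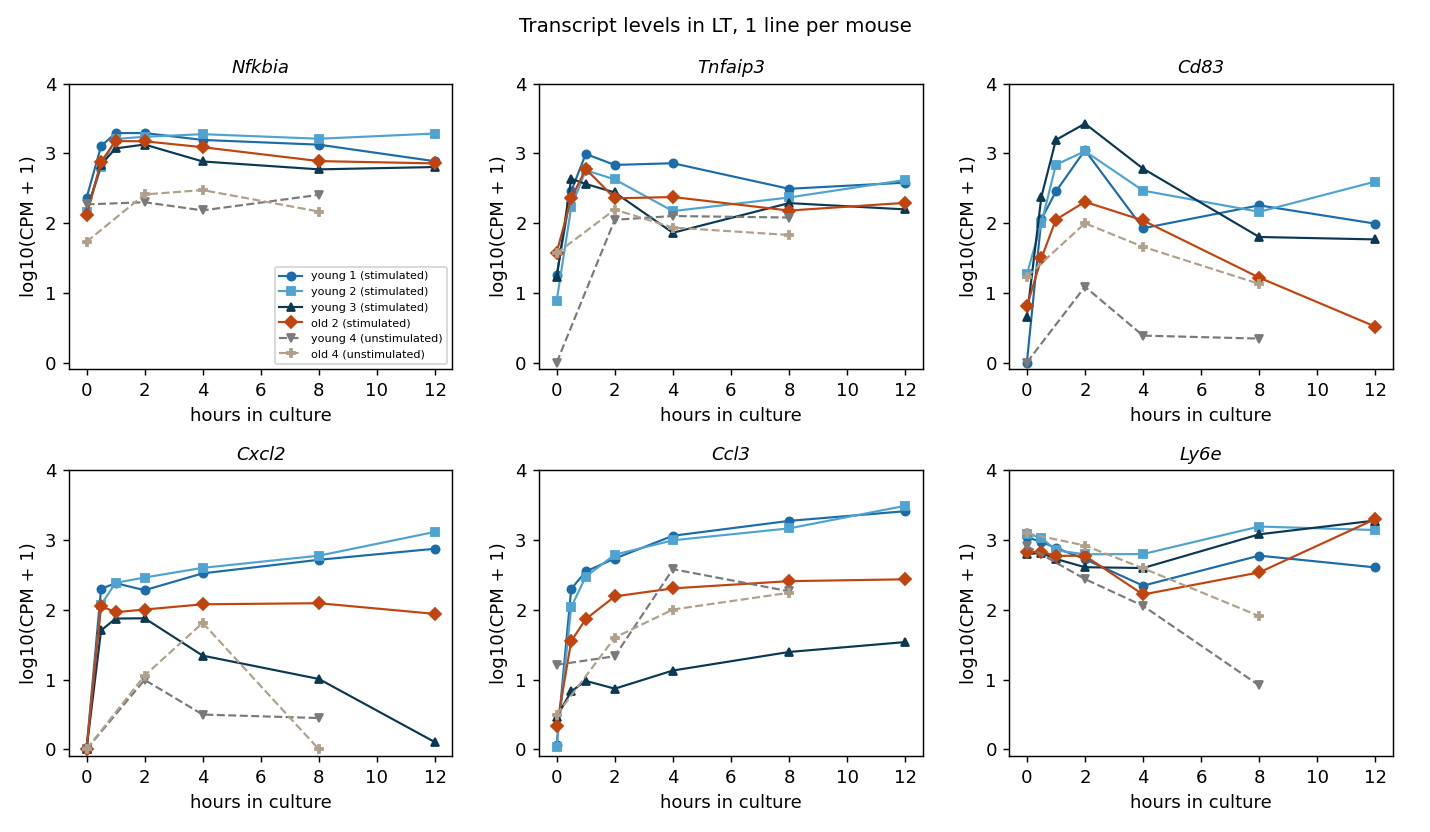
Transcript levels in LT as log10(CPM + 1) against hours in culture, 1 line per mouse, solid with LPS and Pam3csk4 and dashed without. At 2 h Nfkbia averaged 1673 CPM in the 3 stimulated young mice and 227 CPM in the 2 unstimulated mice. Ccl3 of young mouse 3 was at 23.9 CPM at 8 h, against 1885 and 1471 CPM in young mice 1 and 2.

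At 8 h NF-kB genes and chemokines of young LT were above 0 h. Nfkbia was at 1180 ± 532 CPM (n = 3, log2 change 2.82 ± 0.40 SE, edgeR adjusted p = 1.9e-05) and Nfkbiz at 306 ± 213 CPM (4.73 ± 0.58, adjusted p = 1.5e-06). Ccl3 reached 1127 ± 977 CPM (10.81 ± 1.86, adjusted p = 9.3e-04) and Cxcl2 376 ± 320 CPM (at least 2702-fold higher, adjusted p = 0.0063). Cxcl10, a chemokine induced by interferon, rose from 2.04 ± 1.80 to 216 ± 28.0 CPM (adjusted p = 0.023). Of the NF-kB list 8 of 24 genes were higher (18 adjusted over the list alone; adjusted p = 1.3e-09 with an estimated correlation). Of the cytokine list 4 of 30 were (18 higher and 1 lower adjusted over the list alone; adjusted p = 3.0e-05 with an estimated correlation). The p53 target list was higher too (4 higher and 1 lower of 20 adjusted over the list alone; adjusted p = 0.019 with an estimated correlation). Of the 7 genes that fell, Dut, which keeps uracil out of DNA, went from 132 ± 56.7 to 6.79 ± 5.61 CPM (-4.22 ± 0.96, adjusted p = 0.029). The chromatin protein Hmgb1 went from 1186 ± 380 to 451 ± 55.6 CPM (-1.35 ± 0.29, adjusted p = 0.020). Grwd1, a ribosome assembly factor, went from 58.4 ± 48.2 CPM to 0 counts (at least 221-fold lower, adjusted p = 0.0063). The floor covers counting error only. As the 8 h libraries of young mice 1 and 2 had 6241 and 7547 detected genes, dropout of this transcript is not excluded. All 24 ribosome biogenesis genes had a negative fitted change and 5 were lower adjusted over the list alone. Their median log2 change ranged from -4.88 to -1.16 between the young mice. The list passed camera with its preset correlation but had an adjusted p = 0.095 with an estimated correlation, and 0.019 with mouse as a block. Likewise the interferon-stimulated list was higher with the preset correlation, with 33 of 41 members positive (adjusted p = 0.21 with an estimated correlation), and the cell cycle list lower (adjusted p = 0.41 with an estimated correlation). With the preset correlation the cholesterol synthesis, integrated stress response and TLR signalling lists were also higher and erythroid markers lower (adjusted p = 0.21, 0.21, 0.064 and 0.43 with an estimated correlation). With mouse as a block TLR signalling passed with an estimated correlation too (0.038).

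Mice differed in the chemokines that rose in LT, and in the granule transcripts beside them. At 8 h Ccl3 was at 1885 CPM in young mouse 1, 1471 in young mouse 2 and 23.9 in young mouse 3. That mouse had the low granule transcripts (0.0240% of LT counts at 0 h). The sum of the 6 granule transcripts went in LT from 54031 CPM at 0 h to 65688 at 8 h in young mouse 1, from 31247 to 52580 in young mouse 2 and from 240 to 215 in young mouse 3. In MPP it went from 43969 to 78555 CPM, from 20662 to 39144 and from 98.8 to 201. These changes were not tested. Cxcl2 was at 521, 597 and 9.19 CPM. Tnf, which did not pass (780 ± 774 CPM, n = 3, edgeR adjusted p = 0.16), was at 1550, 787 and 2.19 CPM in the same mice. Of the 13678 genes tested in LT at 8 h, 32 were higher and 7 lower, and 1544 had an unadjusted p under 0.05. The numbers called at 0.5, 1, 4 and 12 h were 21, 35, 37 and 33. With mouse as a block 166 passed (91 higher), with DESeq2 796 (231 higher and 565 lower). With limma voom 246 passed, with young mouse 4 added at 0 h 72, and in a fit of the 6 libraries alone 0. Without libraries of fewer than 8000 detected genes, 14 passed; this leaves young mouse 3 alone in LT at 8 h, assumed to vary like the other groups. Without young mouse 1, 22 passed, without young mouse 2, 0, and without young mouse 3, 234.

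ST and MPP answered the ligands with many of the same genes. In ST at 2 h Nfkbia rose from 121 ± 47.4 to 1808 ± 190 CPM (n = 3, log2 change 4.03 ± 0.42 SE, edgeR adjusted p = 4.4e-09). Cxcl16, a membrane-bound chemokine, rose from 0 counts to 160 ± 95.1 CPM (at least 1230-fold higher, adjusted p = 4.7e-04). In MPP at 2 h Nfkbia rose from 104 ± 46.4 to 1422 ± 287 CPM (3.99 ± 0.42, adjusted p = 5.8e-09). Cd83 rose there from 8.12 ± 5.78 to 1144 ± 903 CPM (7.34 ± 1.55, adjusted p = 0.011). At 8 h Ccl3 stood at 1208 ± 1028 CPM in ST and 1176 ± 507 CPM in MPP (adjusted p = 0.022 and 0.012). Hspa5, the chaperone of the endoplasmic reticulum, stood at 1575 ± 448 and 1986 ± 736 CPM against 459 ± 114 and 662 ± 31.5 CPM at 0 h (adjusted p = 0.0016 and 0.0046). In MPP at 8 h the chromatin genes Set (-1.41 ± 0.31) and Hmgb1 (-1.23 ± 0.29) and the tubulin regulator Stmn1 (-1.94 ± 0.46) fell, with adjusted p of 0.019, 0.041 and 0.034. Of the genes higher at 2 h, 27 were shared by LT and ST (0.120 expected of independent lists), 25 by LT and MPP (0.105) and 31 by ST and MPP (0.108). The lists were not independent, as they came from the same 3 mice and 1 fit with a shared estimate of the spread. The excess over these values is thus no test of a shared response. In all, 24 rose in all 3 cell types, among them Cd83, Icam1, Nfkb2, Nfkbia, Nfkbiz, Relb, Tnfaip3 and Traf1.

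The NF-kB list rose in both ST and MPP at 2 and 8 h. In ST 10 of its 24 genes were higher at 2 h and 8 at 8 h (20 and 16 adjusted over the list alone; adjusted p = 1.9e-11 and 4.6e-10 with an estimated correlation). In MPP 10 and 8 were higher (21 and 20 adjusted over the list alone; 3.2e-13 and 3.1e-12). Of the 30 cytokines and chemokines, 5 and 7 were higher in ST and 3 and 6 in MPP (15 and 17, and 15 and 16, adjusted over the list alone). Immediate early genes (6 of 31 in ST and 11 in MPP adjusted over the list alone), heat shock (6 of 16 in each), integrated stress response (4 and 3 of 19) and p53 target genes (5 and 7 of 20) rose at 2 h in both. Their adjusted p were 0.016 or less with an estimated correlation. Without ligand the median log2 change of the heat shock list at 2 h was 2.29 and 1.90 in ST of young mouse 4 and old mouse 4 and 1.97 and 2.51 in MPP. With ligand it was 1.11 ± 0.30 in ST and 1.08 ± 0.20 in MPP (SD, n = 3 young mice). The courses did not differ in this list at 2 h with an estimated correlation (adjusted p = 0.50 in ST and 0.12 in MPP; 0.0046 and 4.3e-06 with the preset one). At 8 h the p53 target list was higher in ST (5 of 20 adjusted over the list alone; 0.0014) and MPP (5 of 20; 7.8e-05), and the integrated stress response list in MPP (1 of 19; 0.0496, and 0.071 with mouse as a block). At 8 h the cholesterol synthesis list was higher in ST (5 of 18 adjusted over the list alone; adjusted p = 0.026 with an estimated correlation) and in MPP (4 of 18; 0.0049). The TLR signalling list was so too (2 of 26 in each; 0.036 and 0.0039). In MPP at 2 h the 3 regulators followed up in the study passed as a list (adjusted p = 0.0088 with an estimated correlation), which is not independent evidence of their direction. Ribosome biogenesis genes were lower at 8 h in ST and MPP with the preset correlation (adjusted p = 0.44 and 0.16 with an estimated correlation). With the preset correlation alone, cell cycle genes were lower in both at 2 and 8 h, interferon-stimulated genes lower in both at 2 h and higher in ST at 8 h, and erythroid markers lower in both at 8 h. So were HSC identity genes and megakaryocyte and stromal markers lower in MPP at 8 h. Higher in MPP in this way were the SOCS and JAK-STAT list at 2 and 8 h, and hypoxia and immediate early genes at 8 h. TLR signalling was higher in MPP at 2 h with the preset correlation (adjusted p = 0.054 with an estimated one, and 0.033 with mouse as a block).

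Totals in ST were 41 higher and 1 lower of 13678 genes at 2 h and 35 and 1 at 8 h by edgeR, and in MPP 36 and 0, and 40 and 3. At 12 h ST had 37 higher and 24 lower genes (269 in all with mouse as a block, 1328 with DESeq2, 615 with limma voom, and 1 in a fit of the compared libraries alone). Most of these lower genes, among them Faf1, Grwd1, Nup107 and Suclg2, were at 0 counts in all ST libraries at 12 h. Those libraries had 7933 to 9405 detected genes, against 10599 to 12564 at 0 h, so dropout of transcripts is not excluded. With mouse as a block the 2 h and 8 h counts were 110 and 125 in ST and 87 and 113 in MPP, and with DESeq2 383 (205 higher), 511 (182 higher), 157 (116 higher) and 218 (122 higher). With limma voom they were 465 and 164 in ST and 1646 and 1761 in MPP. In fits of the 6 compared libraries alone they were 16 and 2 in ST and 422 and 123 in MPP. Without young mouse 2 the counts were 5 and 5 in ST and 4 and 4 in MPP, and without young mouse 3, 69 genes passed in ST at 8 h.

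**Figure D3:**
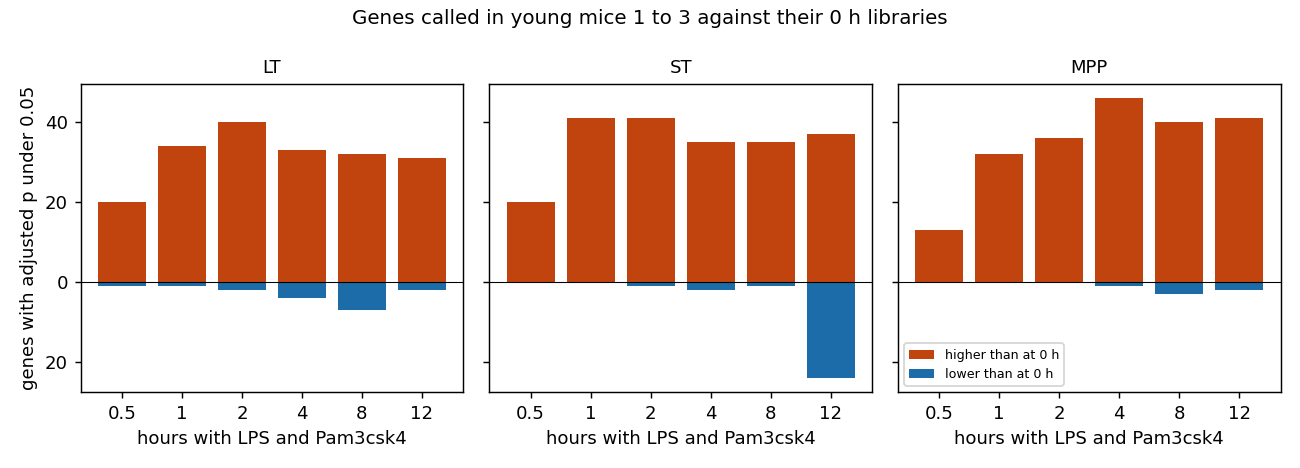
Numbers of genes called by edgeR (adjusted p under 0.05) at each time with LPS and Pam3csk4 against 0 h, in LT, ST and MPP of young mice 1 to 3; bars above 0 count higher genes and bars below 0 lower ones. Most calls were higher genes at each time, for example 40 of 42 in LT at 2 h; ST at 12 h had 37 higher and 24 lower.

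The next comparison asked which changes in LT needed the ligands, by setting the change from 0 h in the stimulated mice (young 1, 2 and 3 and old 2) against that in the unstimulated ones (young 4 and old 4). At 8 h Ly6e, Ifitm2, Icam1 and Nadk stood higher with ligand, relative to 0 h, than without. Ly6e, an interferon-stimulated membrane protein, was at 929 ± 558 CPM at 8 h against 906 ± 304 at 0 h with ligand (n = 4). Without ligand it was at 43.8 ± 51.7 against 1035 ± 306 (n = 2; difference of log2 changes 4.70 ± 0.89 SE, edgeR adjusted p = 0.0085). Ifitm2, an antiviral membrane protein, went from 249 ± 66.1 to 320 ± 164 CPM with ligand and from 178 ± 23.1 to 20.6 ± 11.2 CPM without (3.33 ± 0.61, adjusted p = 0.0061). With ligand Ifitm2 rose in the 3 young mice and fell in old mouse 2 (214 to 93.1 CPM). Ly6e fell in old mouse 2 (664 to 343 CPM) and in young mouse 1 (1103 to 598 CPM). Icam1, an adhesion molecule induced by NF-kB, went from 60.8 ± 18.9 to 347 ± 113 CPM with ligand and from 41.9 ± 29.4 to 3.95 ± 4.74 CPM without (5.92 ± 1.05, adjusted p = 0.0053). Nadk, the kinase that makes NADP, was the other gene that passed (3.78 ± 0.60, adjusted p = 8.7e-04).

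Lists set the stimulated and unstimulated courses of LT apart at both times. At 2 h all 24 NF-kB genes had a larger fitted change with ligand, 7 of them adjusted over the list alone (adjusted p = 4.2e-09 with an estimated correlation). Of 30 immediate early genes 25 did, 1 adjusted over the list alone (0.017). Nfkbia itself went from 160 ± 45.6 to 1627 ± 271 CPM with ligand (n = 4) and from 119 ± 92.9 to 227 ± 41.3 without (n = 2). This difference did not pass (2.35 ± 0.61, edgeR adjusted p = 1.0). Cd14 reached 660 ± 536 CPM with ligand and 531 ± 20.2 without. At 8 h the NF-kB list (9 of 24 adjusted over the list alone; adjusted p = 5.0e-07 with an estimated correlation) and the interferon-stimulated list (16 of 41; 0.0010) were higher with ligand. The integrated stress response list was lower (6 of 19; 0.030, and 0.093 with mouse as a block), with Ddit3 at 39.8 ± 24.97 CPM with ligand and 260 ± 119 without. The cytokine list was higher with ligand at 2 h and 8 h with the preset correlation (adjusted p = 0.25 and 0.43 with an estimated correlation). So were, at 2 h, the interferon-stimulated, p53 target and SOCS and JAK-STAT lists (0.57, 0.25 and 0.25). The heat shock list did not differ at 2 h (4 of 16 positive; adjusted p = 0.31 with the preset and 0.90 with an estimated correlation). Some genes called in stimulated young mice also rose without ligand against 0 h, a comparison chosen after the data were seen. They were Cdkn1a, Sqstm1 and Vmp1 among the 40 of LT at 2 h, and 8 of the 32 at 8 h, with Ftl1, Aldoa and Cdkn1a among them (0.0117 and 0.0538 expected of independent lists). These lists were not independent either, as the fit behind the unstimulated calls also held the stimulated libraries, so the excess is no test. Without ligand only 4 genes were called higher in LT at 2 h and 23 at 8 h, in 2 mice with shallower libraries. Genes outside the overlap were therefore not shown to need the ligands.

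In LT, 0 of 14401 genes passed this comparison at 2 h by edgeR (482 with an unadjusted p under 0.05; DESeq2 186, limma voom 5, and a direct comparison of stimulated with unstimulated libraries 3). At 8 h 4 passed, all higher with ligand. In data simulated for this comparison at 8 h, edgeR found 4.5% of planted log2 changes of 4 and 0 of 67 of those of 2. The comparison at 2 h was not simulated. The low numbers of calls thus do not show that the ligands had no effect. At 8 h the count was 15 with mouse as a block, 475 with DESeq2 (323 higher), 46 with limma voom and 43 in the direct comparison. It was 17 without libraries of fewer than 8000 detected genes and 0 in a fit of the compared libraries alone. Leaving out young mouse 2 gave 0 genes at 8 h, young mouse 1, 24, and young mouse 3, 12. Leaving out old mouse 4 gave 13 and taking young mice only 7, with young mouse 4 as the only unstimulated mouse, assumed to vary like the other groups. At 2 h leaving out young mouse 3 or old mouse 4 gave 1 gene each. At 8 h 19 genes passed in ST and 16 in MPP, with Ifitm2, Nadk, Ly6e and Nfkbia in both. As no mouse had both courses, the ligands cannot be told apart from the mice.

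**Figure D4:**
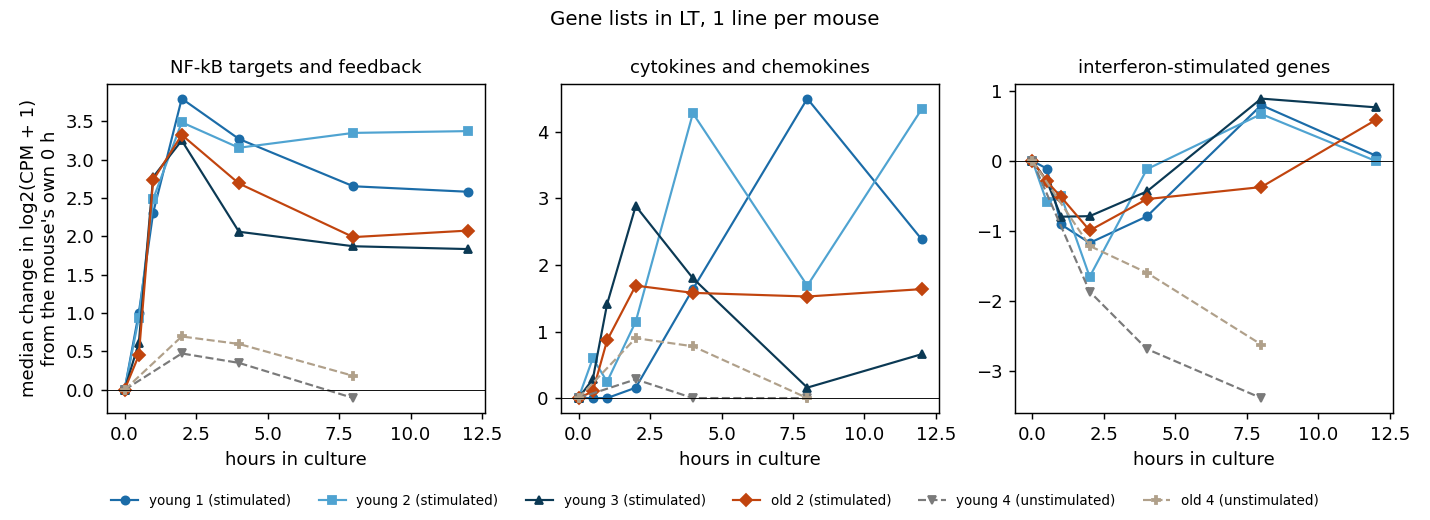
Median change in log2(CPM + 1) from the mouse's own 0 h library over the genes of 3 lists in LT, against hours in culture, 1 line per mouse (solid with LPS and Pam3csk4, dashed without; 0 h is 0 by construction). For the NF-kB list at 2 h the stimulated mice lie between 3.25 and 3.80; for the interferon-stimulated list at 8 h the unstimulated mice lie at -3.39 and -2.62.

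Before culture, LT and MPP of the 4 young mice differed in the list of genes reported as higher in aged HSCs, while no single gene passed by edgeR. Dntt, the terminal transferase of early lymphoid cells, was at 12.3 ± 7.02 CPM in LT and 493 ± 354 in MPP (n = 4 mice; log2 difference -5.28 ± 1.16 SE, edgeR adjusted p = 0.84). Flt3, a receptor by which MPP are often sorted, was at 56.0 ± 54.4 CPM in LT and 466 ± 388 in MPP (log2 difference -3.00, -4.07 without young mouse 1, which was at 136.9 CPM in LT, and -2.14 without young mouse 3), and Cd34 at 154 ± 101 and 772 ± 542 CPM. The transcription factor Gfi1b was at 94.9 ± 13.7 CPM in LT and 36.5 ± 10.2 in MPP. Esam, an endothelial and stem cell adhesion molecule, was at 123 ± 78.9 and 13.2 ± 9.94, Mllt3 at 100 ± 89.9 and 11.4 ± 5.18 and Gata2 at 131 ± 38.7 and 60.3 ± 21.0. Mllt3 in LT was at 229 CPM in young mouse 3, with the nearest mouse at 81.3. The list of MPP and lymphoid priming genes was lower in LT (4 of 19 adjusted over the list alone; adjusted p = 0.030 with an estimated correlation, and 0.098 with mouse as a block). The list of genes reported as higher in aged HSCs was higher in LT (19 of 19 members positive, 0 adjusted over the list alone; 0.0022, and 0.027 with mouse as a block). The HSC identity list was so with the preset correlation, with 27 of 28 members positive and 3 adjusted over the list alone (0.14 with an estimated correlation, and 0.027 with mouse as a block).

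Some markers of other lineages differed between cell types with the preset correlation. With an estimated one only erythroid markers passed, between LT and MPP with mouse as a block. Megakaryocyte and erythroid markers were higher in LT than in MPP with the preset correlation (15 of 17 and 20 of 20 members positive; adjusted p = 0.15 and 0.39 with an estimated correlation, and 0.23 and 0.036 with mouse as a block). So were stromal markers (1 of 10 adjusted over the list alone; 0.39) and immediate early genes (0 of 23; 0.39), while the cell cycle list was lower (0 of 32; 0.88). Against ST, LT were higher in the aged HSC list (2 of 19 adjusted over the list alone; adjusted p = 0.027 with an estimated correlation, and 0.24 with mouse as a block). With the preset correlation they were also higher in stromal markers (2 of 10; 0.46) and HSC identity genes (0 of 28; 0.84). The same held for megakaryocyte markers (1 of 17; 0.68), erythroid markers (0 of 20; 0.88) and the cell cycle list (0 of 32; 0.90). The granule transcripts made up 0.0240% to 6.23% of the LT counts and 0.00988% to 6.44% of the MPP counts of these mice. Of 11568 genes, 0 passed between LT and MPP by edgeR (307 with an unadjusted p under 0.05; DESeq2 39, limma voom 0, mouse as a block 0). Between LT and ST 0 passed by edgeR (323 with an unadjusted p under 0.05; DESeq2 61, limma voom 0, mouse as a block 0). In data simulated for LT against MPP, edgeR found 68.2% of planted log2 changes of 4 and 10.4% of those of 2.

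**Figure D5:**
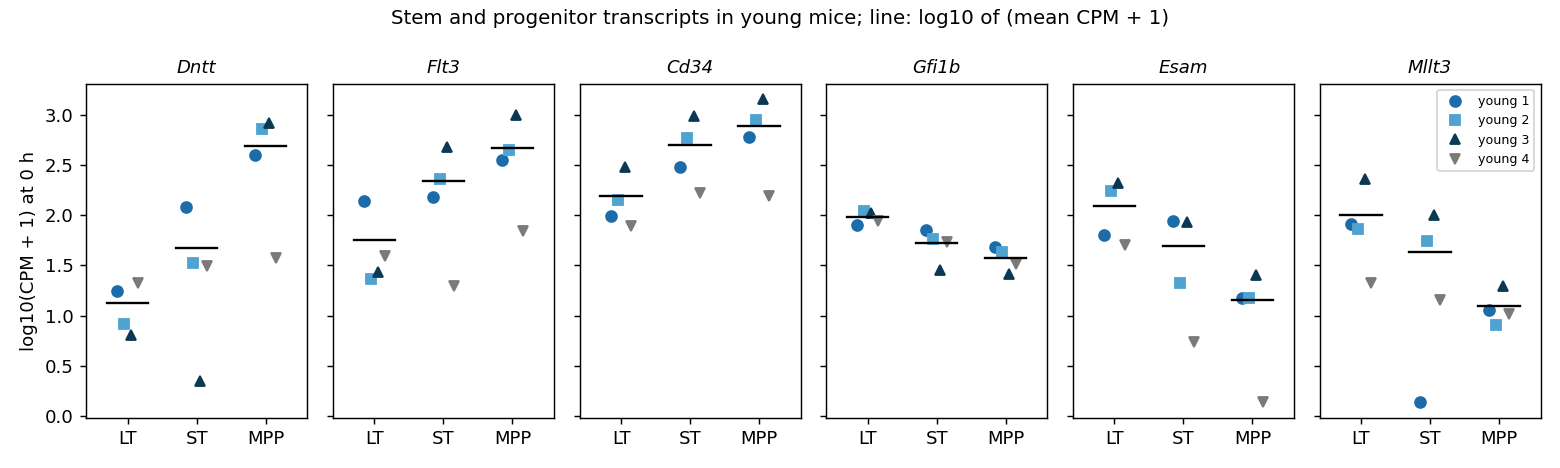
Levels of 6 stem and progenitor transcripts at 0 h as log10(CPM + 1) in LT, ST and MPP of the 4 young mice (1 marker per mouse), with a line at log10 of the mean CPM + 1. Dntt averaged 12.3 CPM in LT and 493 CPM in MPP, and Gfi1b 94.9 and 36.5 CPM.

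Whether LT and MPP answered the ligands differently was tested as the difference of their changes in young mice 1, 2 and 3. Nfkbia rose in both cell types at 2 h (n = 3), and the difference of the log2 changes was -0.64 ± 0.52 (SE; edgeR adjusted p = 1.0). Ebi3, a cytokine subunit of the interleukin 12 family, was at 205 ± 71.2 CPM at 8 h against 128 ± 8.69 at 0 h in LT. In MPP it was at 632 ± 137 against 69.6 ± 16.0 CPM (difference of log2 changes -2.61 ± 0.57, adjusted p = 0.49). Tnf at 8 h was at 780 ± 774 CPM in LT and 259 ± 180 CPM in MPP (difference of log2 changes 1.52 ± 2.23, adjusted p = 1.0). The interferon-stimulated list rose more in LT than in MPP at 8 h with the preset correlation (31 of 41 members positive; adjusted p = 0.99 with an estimated correlation). By edgeR 0 of 13678 genes passed at 2 h (336 with an unadjusted p under 0.05; DESeq2 225, limma voom 0, mouse as a block 0). At 8 h 0 passed by edgeR (441 with an unadjusted p under 0.05; DESeq2 310, limma voom 17, mouse as a block 0, and 2 without libraries of fewer than 8000 detected genes, which leaves young mouse 3 alone in LT). Without young mouse 3, 9 genes passed at 2 h and 36 at 8 h, and without young mouse 1, 1 at 8 h.

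The last comparisons concerned age. At 0 h no gene passed by edgeR between the 2 old and the 4 young mice, and 1 list did with an estimated correlation, in MPP. In data simulated for old against young LT, edgeR found 57.6% of planted log2 changes of 4 and 11.9% of those of 2. Of 23 lists, 0 had an age difference that differed between LT and MPP (lowest adjusted p = 0.058 with the preset and 0.98 with an estimated correlation). Selp, the adhesion receptor P-selectin and a gene reported as higher in aged HSCs, was at 125 ± 130 CPM in old LT (n = 2) and 25.1 ± 38.2 in young LT (n = 4; log2 difference 2.28 ± 1.29 SE, edgeR adjusted p = 1.0). Young mouse 2 was at 81.7 CPM and the nearest young mouse at 14.5, and without young mouse 2 the log2 difference was 4.27. The old mice were at 217 and 33.0 CPM, and without old mouse 2 it was 0.40. Aldh1a1, an aldehyde dehydrogenase of the same list, was at 98.9 ± 45.2 and 34.9 ± 9.27 CPM in LT and at 41.2 ± 26.8 and 9.43 ± 5.93 CPM in MPP. The list reported as higher in aged HSCs was higher in old MPP (22 of 26 members positive, 0 adjusted over the list alone; adjusted p = 0.021 with an estimated correlation). In old LT (21 of 26 positive, 0 adjusted over the list alone) and old ST (16 of 26, 1 adjusted over the list alone) it was higher with the preset correlation (0.49 and 0.71 with an estimated correlation). Megakaryocyte markers were higher in the same way in old LT (15 of 19 positive; 0.49) and old MPP (14 of 19; 0.15), and erythroid markers in old MPP (16 of 20; 0.64). The MPP and lymphoid priming list (3 of 19 positive, 0.15 with an estimated correlation) and cytokines (4 of 17, 0.19) were lower in old MPP with the preset correlation only. Interferon-stimulated genes were lower in old MPP (12 of 41 positive; adjusted p = 0.13 with an estimated correlation) and old ST (12 of 41; 0.71) with the preset correlation. Stromal markers were lower in old LT in the same way (3 of 13 positive; 0.49), with Cxcl12 at 2.58 ± 3.65 CPM in old and 230 ± 251 in young LT. By edgeR 0 of 12983 genes passed in LT (440 with an unadjusted p under 0.05; DESeq2 19, limma voom 0), 0 in ST (551; DESeq2 74, limma voom 0) and 0 in MPP (56; DESeq2 3, limma voom 0). Without old mouse 2, 2 genes passed in ST, with old mouse 4 assumed to vary like the other groups.

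The response of old LT was measured in 1 stimulated old mouse, so its values stand beside the young ones with no test. The median log2 change of the 24 NF-kB genes at 2 h was 3.32 in old mouse 2 and 3.51 ± 0.27 in the young mice (SD, n = 3; 3.25 to 3.80), a difference of -0.19. The unstimulated mice stood at 0.47 and 0.70. The cytokine list changed by 1.69 in the old and 1.40 ± 1.38 in the young mice. The interferon-stimulated list stood at -0.37 in old mouse 2 and 0.79 ± 0.11 in the young mice at 8 h, and at 0.59 and 0.28 ± 0.42 at 12 h. At 8 h it stood at 1.44 in the old and -0.04 ± 0.57 in the young mice in ST, and at 0.97 and 0.10 ± 0.83 in MPP. Over 23 lists at 6 times, the old mouse lay outside the range of the 3 young ones in 49 of 138 values in LT, 60 in ST and 56 in MPP. A mouse like the other 3 in all respects would be expected outside their range in 69 of 138.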

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

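The tests on cytokine ratios, on batches, on the direction of granule transcripts between cell types, and on splits of the cell type and response-difference comparisons were chosen after their results were seen; the other tests were planned. Of 42 groups of libraries tested, 3 had a library standing apart by Dixon's test, which chance does in about 1 in 20 groups. Flt3 in young LT at 0 h was at 136.9 CPM in young mouse 1, with the nearest mouse at 38.4 CPM. Selp in the same group was at 81.7 CPM in young mouse 2, with the nearest mouse at 14.5 CPM. In young MPP at 0 h, young mouse 4 had 11912 detected genes and the nearest mouse 13253. The change from 0 to 12 h differed between LT and ST of young mice for 1 gene, Faf1, which was at 33.3 ± 40.9 CPM at 12 h and 33.8 ± 45.0 at 0 h in LT, and at 0 and 50.5 ± 37.1 CPM in ST (n = 3, edgeR adjusted p = 0.036). The ST libraries had 7933 to 9405 detected genes at 12 h, against 10599 to 12564 at 0 h. Dropout of the transcript was not told apart from a different response. The interferon-stimulated list changed by -0.37 in LT of old mouse 2 at 8 h and by 0.67 to 0.89 in the 3 young mice; this difference was not tested. At 12 h in LT the old mouse lay within the young range (0.59; 0 to 0.77), and at 8 h in ST above it (1.44; -0.60 to 0.53).

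Granule transcripts made up 1.68% to 6.44% of the counts at 0 h in 5 mice and 0.00988% to 0.0240% in young mouse 3. Expression that differs between the sorted types stays open: the log2 ratio of the 6-gene sum in MPP to LT had a median of -0.24 (-1.28 to 0.05), with more in MPP in 1 of 6 mice. RNA or cells of granulocytes in the sorted samples may be the source, since the 6 genes kept near 1 ratio across the cell types of a mouse (median difference of log2 shares 0.143, against 0.304 between mice). Equal expression in all 3 types would give the same and stays open, and batches of mice or days cannot be told apart from the mice, as 0 of 5 column tags held mice on both sides and 1 held more than 1 mouse.

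Cytokine transcripts at 8 h were lower in young mouse 3 than in young mice 1 and 2. The median ratio over expressed list members was 0.0973 in LT (17 of 21 lower), 0.345 in ST (18 of 20) and 0.541 in MPP (18 of 21), while granule transcripts stood at 0.00364, 0.00929 and 0.00342. At 2 h the medians were 0.553 (13 of 17), 0.549 (14 of 20) and 0.836 (9 of 15), with granule transcripts at 0.00167, 0.00228 and 0.00291. The bounds for these medians were set after the values were seen, so lying beyond them is no test. At 2 h in LT, ST and MPP and at 8 h in ST and MPP the list median was lowered far less than the granule transcripts. This argues only against RNA or cells of granulocytes as the sole source of the list's transcripts there. A part from granulocytes that accounts for the difference between the mice stays open. Single members are not covered by this. In LT Ccl3 lay under the bound set for that source, at 0.0110 at 2 h and 0.0142 at 8 h. Cxcl2 and Tnf were also far lower in LT of this mouse at 8 h. For these genes in LT that source stays open. For the list in LT at 8 h, RNA or cells of granulocytes cannot be told apart from a weaker response of this mouse, since the median ratio lay between the bounds set for either. No biological explanation for a difference between young mice was tested.

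In unstimulated LT the interferon-stimulated list fell by 3.39 on the log2 scale in young mouse 4 and by 2.62 in old mouse 4 from 0 to 8 h. Dropout of transcripts in libraries of low complexity was argued against, as both medians lay at percentile 0 of 10000 lists matched on mean expression, whose medians were -0.42 and -0.36. With ligand the list also fell in LT at 2 h, with medians of -1.66 to -0.79 in the 3 young mice and -0.99 in old mouse 2. An early fall was therefore not particular to culture without ligand. For 8 h, loss of an interferon signal in culture without ligand stays open as a hypothesis. Batches of mice or days cannot be told apart from it in the comparison with stimulated LT, because 0 mice had both courses.

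Other splits of the same libraries were counted in fits of those libraries alone. For changes from 0 h the 10 splits are too few for a share under 0.05: the real split gave 16 and 2 genes in ST at 2 and 8 h and 422 and 123 in MPP (highest other 0 in each). Where the real split gave 0 genes, every split reaches that number whatever the data, so the count decides nothing. This was so in LT at 2 and 8 h (10 splits, highest other 0 in each) and for the difference between LT and MPP responses (10 splits, highest other 1 at 2 h and 14 at 8 h). It was so at 0 h for LT against MPP (35 splits, highest other 2) and LT against ST (35 splits, highest other 3). The 14 genes at 8 h set LT of young mice 1 and 2 and MPP of young mouse 1 against the other courses, and a structure of the samples behind it was not tested.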

How the results depend on the processing

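The minimum of 8000 detected genes, ST at 12 h without its shallowest library (58 genes, against 61) and the granule share as a covariate at 0 h (0 genes for LT against MPP and ST) were chosen after seeing the data, and the other alternatives were planned. The edgeR counts in LT, ST and MPP at 2 and 8 h were 42 and 39, 42 and 36, and 36 and 43. DESeq2 gave 559, 796, 383, 511, 157 and 218 in that order; limma voom 246 in LT at 8 h, 465 and 164 in ST and 1646 and 1761 in MPP. Mouse as a block gave 101, 166, 110, 125, 87 and 113 and kept every main call; the compared libraries alone gave 0, 0, 16, 2, 422 and 123. With at least 8000 detected genes per library, 65 and 14 genes passed in LT, 81 in ST at 2 h, and 76 and 68 in MPP. With young mouse 4 at 0 h, 64 and 72 passed in LT, and at 2 h 69 in ST and 60 in MPP. Leaving out each mouse gave 5 to 112 and 0 to 234 in LT, 5 to 53 and 5 to 69 in ST, and 4 to 43 and 4 to 62 in MPP; the lowest count was without young mouse 2 in each. For stimulated against unstimulated LT at 2 h (edgeR 0), DESeq2 gave 186, limma voom 5, the direct comparison 3, and leaving out each mouse 0 to 1. At 8 h (edgeR 4) DESeq2 gave 475, limma voom 46, the block 15, the compared libraries alone 0, the 8000-gene minimum 17, young mice only 7, the direct comparison 43, and leaving out each mouse 0 to 24. For LT against MPP and ST at 0 h DESeq2 gave 39 and 61, and leaving out each mouse 0 to 0. For the response difference DESeq2 gave 225 at 2 h and 310 at 8 h; at 8 h limma voom gave 17 and the 8000-gene minimum 2; leaving out each mouse gave 0 to 9 and 0 to 36. For age DESeq2 gave 19 in LT, 74 in ST and 3 in MPP, and leaving out each mouse 0 to 0, 0 to 2 and 0 to 0. The NF-kB difference of old mouse 2 was -0.19 by the median and -0.47 by the mean (-0.32 to -0.05 without each young mouse). Where a setting left 1 library in an arm (the 8000-gene minimum in LT at 8 h, no old mouse 4 or young mouse 4 in the unstimulated course, young mice only, no old mouse 2 or 4 for age), that library is assumed to vary like the other groups. Of 345 list tests 95 passed with the preset and 42 with an estimated correlation. Of 276 with mice in common, 41 passed so, and 43 with mouse as a block. With the block the regulators in LT at 2 h (0.048), ribosome biogenesis and TLR signalling in LT at 8 h (0.019 and 0.038), TLR signalling in MPP at 2 h (0.033), and HSC identity and erythroid markers in LT against MPP (0.027 and 0.036) passed newly. The integrated stress response in MPP at 8 h (0.071) and in stimulated against unstimulated LT at 8 h (0.093), lymphoid priming in LT against MPP (0.098) and the aged HSC list in LT against ST (0.24) no longer passed. DESeq2's size factors moved the median change of all genes at 2 h in MPP from -0.21 to -0.39 and in ST from -0.22 to -0.36. A minimum of 20% of the median total removed 0 libraries. Of 1453 values of 108 named genes and comparisons under alternatives, 1175 kept their direction and side of the threshold, 45 passed it newly, 220 no longer passed, and 13, none of them called, changed sign or went to 0. The cause of these differences was not tested. In simulated LT data at 2 h edgeR found 0 of 67 planted log2 changes of 2, so changes of that size were mostly not detectable.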

Other observations

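Comparisons of unstimulated cells with their own 0 h libraries, and the test of the hypothesis on them, were chosen after the data were seen. Stress genes rose in culture without ligand (edgeR, n = 2 mice). At 8 h Sqstm1, an autophagy receptor, went in LT from 171.1 to 3401 CPM in young mouse 4 and from 248.9 to 3673 in old mouse 4 (log2 change 4.28 ± 0.50 SE, adjusted p = 2.6e-07). Ftl1, the ferritin light chain, went from 2606 to 42260 and from 2395 to 30270 CPM (4.04 ± 0.72, adjusted p = 0.0015). Atf4 (2.54 ± 0.45, adjusted p = 0.0015), Ddit3 (5.08 ± 1.13, adjusted p = 0.022) and the amino acid transporter subunit Slc3a2 (4.37 ± 0.79, adjusted p = 0.0020), all of the integrated stress response, rose in LT as well. That list was higher at 8 h in LT (7 of 19 adjusted over the list alone; adjusted p = 8.6e-04 with an estimated correlation), ST (7; 9.0e-04) and MPP (4; 0.0028). Heat shock genes were higher at 2 h in LT (8 of 16 adjusted over the list alone; adjusted p = 3.9e-04 with an estimated correlation), ST (11; 7.9e-05) and MPP (12; 2.8e-06).

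The NF-kB list also rose without ligand at 2 h, in LT (1 of 24 adjusted over the list alone; adjusted p = 3.8e-04 with an estimated correlation), ST (6; 4.8e-04) and MPP (4; 6.3e-06). In MPP the endothelial protein C receptor Procr went from 0 to 78.1 CPM in young mouse 4 and from 0 to 126.3 in old mouse 4 at 8 h (edgeR adjusted p = 0.0055), and the class II gene H2-Aa from 101.5 and 119.5 CPM to 0 (adjusted p = 0.0023). Genes called at 8 h without ligand numbered 34 of 14401 in LT (23 higher), 47 in ST (27 higher) and 43 in MPP (29 higher).

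A loss of interferon-stimulated transcripts in culture without ligand was tested as a hypothesis. The fall in LT (17 of 41 adjusted over the list alone; adjusted p = 0.019 with an estimated correlation) prompted it and is no test of it. In both of the other 2 cell types the list was lower at 8 h than at 0 h, ST (8; 0.049) and MPP (12; 0.014). Ly6e fell by 4.52 in LT, 3.23 in ST and 3.37 in MPP on the log2 scale. These ST and MPP came from the same 2 mice and the same fit as the LT, so they are no independent test. The loss may extend beyond LT within these 2 mice, which had no stimulated course. At 2 h the list was also lower in stimulated LT, with medians of -1.66 to -0.79 in the young mice and -0.99 in old mouse 2. A fall at that time was thus not particular to culture without ligand.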
